A study of Mus musculus with 8 samples.

How the data were processed

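The data are 8 Agilent 1-colour arrays (Cy3 label, per the labels) of total RNA from small and large intestine of claudin-7 knockout and wild-type mouse pups at 3 days of age. Groups were taken from the sample titles, which name genotype, segment and a number (2 or 3), and each of the 4 groups holds 2 arrays. Per the file headers, the deposited array files hold spot intensity from Agilent Feature Extraction 10.7.3.1, background-subtracted and detrended within each array by the scanner software and not scaled between arrays, with probe positions on mouse build mm9. The authors also gave normalized values for each probe, as intensity on a linear scale. Its columns have medians of 158.06 to 160.06, and on the log2 scale each column correlated with its own array's signal at r of at least 0.991 across probes. The near-equal medians show a scaling between arrays, and its background step stays unknown. R 3.3.0 is named per the submitters' processing notes, and the other steps are not given in the sources used here.

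From the scanner files, log2 of the processed signal was taken minus each array's 75th percentile over its 59305 non-control spots (2642.5 to 3571.77 in signal units). Spots with an outlier flag were left out (148 to 312 per array), and spots of the same probe were averaged. Of 55681 non-control probes, 302 were dropped for a flag, and the remaining ones were kept when well above background on both arrays of at least 1 group. Probes were named through the accession in the file (26056 probes), through a current symbol (3200) or an older symbol (930), against a gene table of 49997 genes of assembly GRCm38.p6, used only for names. The file's own name was kept for 2418 probes, and 23077 have no gene name. After the filters 25995 named probes remained, and 1 probe stood for each gene, the one with the highest mean over the 8 arrays, which gave 20001 genes. Among the named genes the kept probes of a gene moved the same way, except for Tpm1 in the small intestine (4 of 5 probes). Pramel34 had 1 kept probe, and a probe of it that the outlier flags removed read the other way.

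The groups were compared in limma 3.58.1 (R 4.3.3, data.table version 1.17.8) with 1 mean per group over all 8 arrays, so that the groups share 1 estimate of spread with 4 residual degrees of freedom, and with empirical Bayes moderation. Contrasts were knockout minus wild type in each segment, large minus small intestine in each genotype, and the difference of the knockout effect between segments. Knockout was compared with wild type over both segments in a fit with genotype and segment as additive terms (5 residual degrees of freedom). P-values were adjusted by the Benjamini-Hochberg method within each comparison, and a gene passed at an adjusted p under 0.05. Agreement of the segments was measured by correlations across genes and by Fisher's exact test (two-sided) on the overlap of genes that passed. In a replicate group the log2 values of the 2 arrays correlated across genes at 0.985 (wild-type small intestine), 0.980 (knockout small intestine), 0.991 (wild-type large intestine) and 0.982 (knockout large intestine).

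Before the data were examined, 51 gene lists, the comparisons, the alternatives and the rule for named genes were fixed. The rule names Cldn7, then for each knockout comparison the 10 largest rises and the 10 largest falls among genes that passed, for the difference between segments 5 each way, and for large against small intestine in wild type 10 each way, passing over clone and predicted-locus names. It adds up to 4 members with the smallest p of each list that passed, and of the claudin, stem cell, goblet cell, metalloproteinase and inflammatory lists in every case. Other genes in the text are further list members, genes shared by the segments, or genes chosen after their values were seen (Alb, Amy2a5, Xist and the Y-linked genes, Zbtb16, Fkbp5, Pck1, Pdx1, Ccl28, Cdx2, S100g, Elp5, Eno3, Nlrp1c-ps). Some genes that the rule selects are not reported here. Lists with at least 5 measured members were tested with camera at a preset correlation between genes of 0.01, with the Benjamini-Hochberg adjustment over the 51 lists. Camera was repeated with a correlation estimated for each list, and fry, a rotation test of whether the genes of a list move one way on balance without setting them against other genes, was run beside it. List medians use the fitted values of all measured members, including members near background.

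The alternatives were normexp background correction (offset 50) of the mean spot signal with the median local background, quantile normalization, the deposited normalized table, no filter on background, only probes well above background on all 8 arrays, outlier flags ignored, the mean of a gene's probes, a trended and robust prior, the replicate number, which is also the slide row, as a fixed block, an animal block, the 2 compared groups alone, a 2-fold threshold, and each array left out in turn. One more, dropping both knockout arrays numbered 3, was chosen after seeing the data. A slide or scan block could not be run, since the files show 1 slide and 1 scan date.

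The pipeline was run on simulated data with the genes' wild-type means in each segment, 1 pooled spread per gene, no genotype effect, and then 200 of 20001 genes shifted. At 4-fold, 84% (small intestine), 72% (large intestine) and 96% (both segments) were recovered, and at 2-fold 10%, 4% and 36%. Of 153, 136 and 170 genes that passed, 6, 6 and 7 were unshifted. A list shifted by 1 (log2) passed in all 3, and 0 other lists did. Noise was drawn per gene, so list calls among correlated genes were not tested.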

Results

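The series holds 8 single-colour microarrays of intestinal RNA from mouse pups of the 129SV strain at 3 days of age. Pups lacking claudin-7, a protein of epithelial cell junctions, were set against wild-type pups. Each pup group gave samples of the small and of the large intestine, so that 4 groups stand side by side, with 2 arrays in each group (replicates 2 and 3). The number of arrays limits the precision: the median standard error of a log2 fold change was 0.28 within a segment. Fold changes are on the log2 scale as estimate ± standard error, with n = 2 arrays per group unless another n is given. "Passed" means an adjusted p under 0.05 in limma. With 2 arrays per group the p-values measure the spread between samples, whose source is not known, and the labels do not say which samples came from one animal.

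Some arrays stood apart in transcripts of other tissues or sex chromosomes (log2 of signal over the array's 75th percentile). Xist, expressed from the inactive X chromosome, read -2.42 and -2.43 on the knockout arrays numbered 3 and -7.46 to -6.25 on the other 6 arrays. The Y-linked genes Ddx3y and Eif2s3y read -9.001 to -8.47 and -6.57 to -5.57 on those 2 arrays, against 0.70 to 1.33 and 2.68 to 3.22 on the others. Alb, encoding serum albumin, read 5.23 on knockout large intestine replicate 2 and -8.38 to -4.53 elsewhere. Amy2a5, a pancreatic amylase, read 2.30 on wild-type large intestine replicate 2 and 2.05 on knockout large intestine replicate 3, against -9.21 to -3.86 on the remaining 6. All 8 arrays lay on 1 slide with 1 scan date. Each group filled 1 slide column, so column and group cannot be told apart, and arrays numbered 2 filled slide row 1 and those numbered 3 row 2.

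The targeted gene was examined first. Cldn7 is represented by 1 probe, on chromosome 11 at 69781255 to 69781314 (mouse build mm9), and whether this probe lies in the deleted part is not known. Its signal fell by 4.34 ± 0.39 in the knockout small intestine (20.2-fold, adjusted p = 0.00794) and fell by 3.52 ± 0.39 in the knockout large intestine (11.4-fold, adjusted p = 0.0338). Over both segments Cldn7 fell by 3.93 ± 0.30 (n = 4 arrays per genotype, 15.2-fold, adjusted p = 0.00979). Cldn7 was well above background on all 8 arrays. The large intestine value did not pass when 1 large intestine array was left out. The adjusted p was then 0.231 without wild-type replicate 2, 0.300 without wild-type replicate 3, 0.104 without knockout replicate 2 and 0.0790 without knockout replicate 3. It did not pass without a background filter (0.0570) or with slide row as a block (0.0719) either, and over the alternatives it ran from 0.00816 to 0.300. The small intestine value did not pass with the 2 compared groups alone (adjusted p = 0.0764). Over both segments it did not pass without wild-type large intestine replicate 2 (0.0514) or 3 (0.0636), within a range of 0.00199 to 0.0636.

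**Figure D1:**
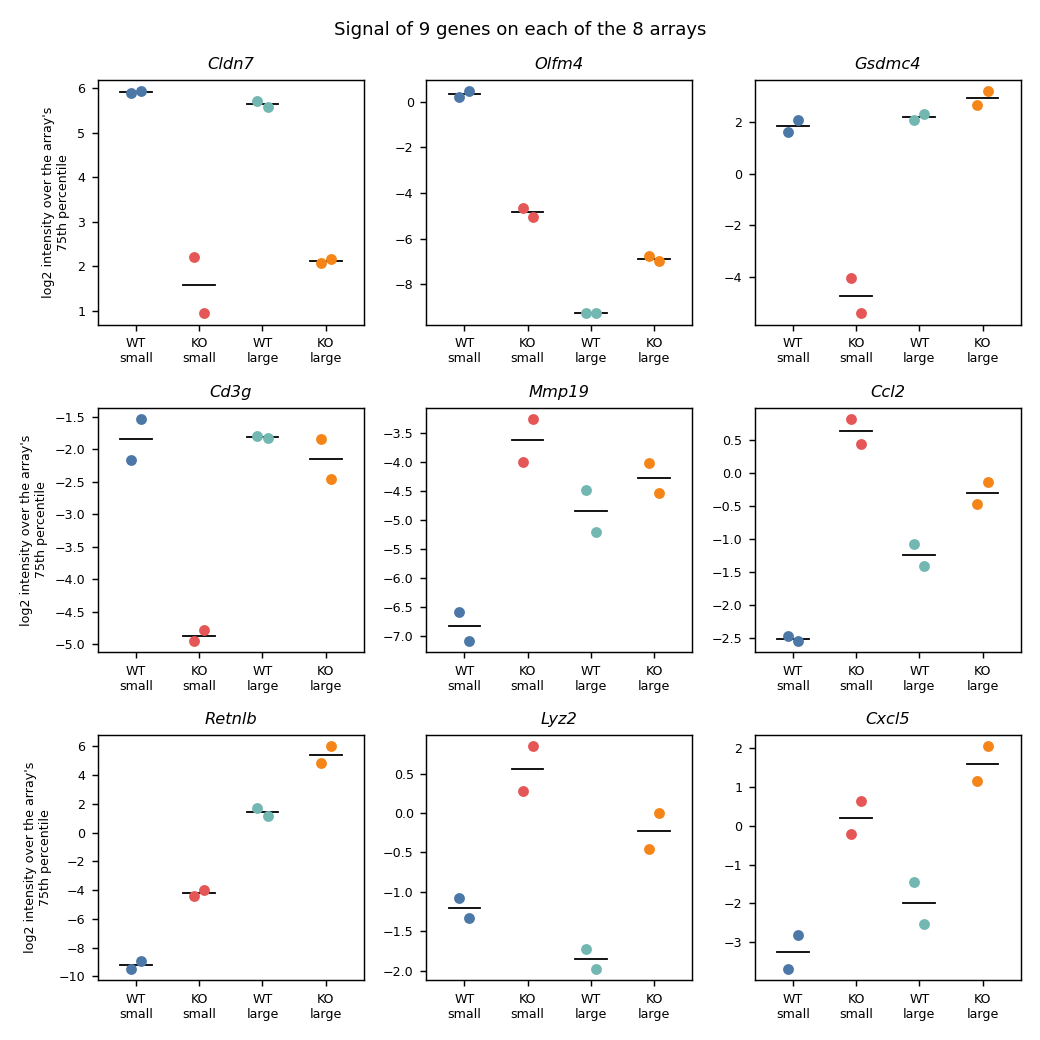
Signal of 9 genes on each of the 8 arrays, as log2 over the array's 75th percentile (vertical axis), by group (horizontal axis), with 1 point per array and a bar at the mean of each group of 2. Cldn7 lies between 0.94 and 2.21 on the 4 knockout arrays and between 5.56 and 5.93 on the 4 wild-type arrays.

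The comparison of knockout with wild-type small intestine asks which transcripts depend on claudin-7 in that segment. In the knockout, the lists of enteric neuron, glia and smooth muscle genes, of inflammatory cytokines and of matrix metalloproteinases shifted up, and the list of T and NK cell genes shifted down (adjusted p = 0.449 with an estimated correlation for each of the 6, so that these calls are lost). Olfm4, a glycoprotein of crypt base cells, fell by 5.17 ± 0.22 (adjusted p = 0.002), and Lgr5, the Wnt-coupled receptor that marks intestinal stem cells, fell by 2.21 ± 0.27 (adjusted p = 0.0171). Ccl2, a chemokine that attracts monocytes, rose by 3.15 ± 0.24 (adjusted p = 0.00462), and Mmp19, a matrix metalloproteinase, rose by 3.21 ± 0.38 (adjusted p = 0.0163). Of 20001 genes tested, 2006 passed, of which 1295 were higher and 711 lower in the knockout.

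Among the 10 largest rises in the small intestine, Anxa10, an annexin of gastric epithelium, rose by 7.92 ± 1.08 (242-fold, adjusted p = 0.0225), and Tmprss15, the enteropeptidase that activates trypsinogen, rose by 7.499 ± 1.14 (adjusted p = 0.0254). Vsig1, a gastric immunoglobulin-type protein, was at least 17.8-fold higher (adjusted p = 0.0323). Such a bound is given where neither array of the dimmer group was well above background. It sets the mean of the brighter group against the mean, per array, of the higher of the gene's own signal and the lowest signal well above background. Clec4e, a lectin receptor of myeloid cells, was at least 30.3-fold higher (adjusted p = 0.0211), Mmp3 (stromelysin-1) at least 22.2-fold (adjusted p = 0.036) and Pla2g2a, a secreted phospholipase A2 with antibacterial activity, at least 16.9-fold (adjusted p = 0.00338). Saa3, an acute-phase serum amyloid, rose by 5.75 ± 0.88, the dicarboxylate transporter Slc13a3 by 5.66 ± 0.58, Gml by 5.48 ± 0.64 and Gfap, the intermediate filament of glia, by 5.12 ± 0.80 (adjusted p = 0.0119 to 0.0268). The 10 largest falls held 3 gasdermin C genes: Gsdmc3 (-6.82 ± 0.56), Gsdmc4 (-6.58 ± 0.46) and Gsdmc (-4.87 ± 0.32), with adjusted p of 0.00338 to 0.00641. Falls were also seen for Sdr16c5, a retinol dehydrogenase (-6.21 ± 0.67), Il22ra2, the soluble binding protein of interleukin-22 (-5.80 ± 0.78), and Dct, an enzyme of melanin synthesis (-5.64 ± 0.60). Nr2e3 (-4.995 ± 1.08), Dio3os (-4.99 ± 0.36), the kinesin gene Kif12 (-4.78 ± 0.33) and Olfm4 complete the list. The adjusted p of these 6 genes besides Olfm4 lay between 0.00338 and 0.0408. Tmprss15 and Mmp19 were well above background on 1 of the 2 wild-type arrays, and Sdr16c5 on 1 of the 2 knockout arrays.

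The fixed lists were tested with camera (51 lists, 922 of their 957 genes measured). In the small intestine 27 passed, 19 up and 8 down. With a correlation estimated for each list camera passed 0 of 51 in every comparison, even wild-type large against small intestine. It may lack power with 8 arrays, so a call lost by it stays undecided. It gave 4 lists here at an unadjusted p under 0.05, and fry gave 9 after adjustment. Each list is given with its members that passed over all genes, the median log2 fold change, and camera's adjusted p.

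All 18 smooth muscle genes lay above 0 and 3 rose, among them Pgm5 (1.94 ± 0.37) and the actin-binding Tagln (1.09 ± 0.26), while 18 rose when adjusted over the list alone (median 1.57, adjusted p = 7.31e-08, adjusted p = 0.449 with an estimated correlation). Of 18 enteric neuron genes 9 rose, 16 adjusted over the list alone, among them the neuropeptide gene Vip (2.25 ± 0.37) and the receptor gene Ret (1.54 ± 0.29). The median was 1.80 (adjusted p = 7.31e-08, adjusted p = 0.449 with an estimated correlation). Of 12 enteric glia genes 8 rose and 1 fell, the same counts when adjusted over the list alone. The receptor gene Erbb3 fell by 1.37 ± 0.25 (median 1.99, adjusted p = 0.000639, adjusted p = 0.449 with an estimated correlation). Of 8 genes of the interstitial cells of Cajal, the pacemaker cells of the gut, 3 rose, 6 adjusted over the list alone (Thbs4 by 1.95 ± 0.39; median 1.37, adjusted p = 0.00207, adjusted p = 0.449 with an estimated correlation). The fibroblast and matrix list had 4 of 22 members higher, 14 adjusted over the list alone, such as Pdgfra (1.02 ± 0.21) and Dcn (0.97 ± 0.20). The median was 0.996 (adjusted p = 1.51e-07, adjusted p = 0.449 with an estimated correlation). Among 18 endothelial genes 0 passed, also when adjusted over the list alone. The median was 0.41 (adjusted p = 0.00207, adjusted p = 0.456 with an estimated correlation). Of 14 adipocyte and mesentery genes 5 rose, 7 up and 1 down adjusted over the list alone, led by the mesothelial gene Msln (1.64 ± 0.26) and by Wt1 (2.32 ± 0.52). The median was 0.76 (adjusted p = 0.0178, adjusted p = 0.449 with an estimated correlation). The 2 wild-type arrays differed here too: the median of the smooth muscle list relative to each gene's mean over the 8 arrays was -1.49 on replicate 3 and -0.38 on replicate 2.

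Of 27 genes of inflammatory cytokines and acute response 11 rose (14 up and 1 down adjusted over the list alone). The median was 1.20 (adjusted p = 7.87e-05, adjusted p = 0.449 with an estimated correlation). Besides Ccl2, those that rose were led by the chemokine genes Ccl7 (3.28 ± 0.35) and Cxcl5 (3.45 ± 0.53) and by Il1rn (3.58 ± 0.46), the antagonist of the interleukin-1 receptor. Of 20 matrix metalloproteinases and inhibitors 10 rose, 13 adjusted over the list alone, including Adamts1 (2.19 ± 0.29), Mmp15 (1.25 ± 0.22) and the inhibitor gene Timp1 (2.26 ± 0.40). The median was 1.25 (adjusted p = 3.65e-07, adjusted p = 0.449 with an estimated correlation). Of 23 genes of epithelial antimicrobial defence 6 rose, 9 adjusted over the list alone, among them Saa1 (2.42 ± 0.47) and Sprr1a (3.15 ± 0.49). The median was 0.83 (adjusted p = 0.000865, adjusted p = 0.449 with an estimated correlation). The epithelial repair and fetal-type program had 7 of 23 members higher, 12 up and 1 down adjusted over the list alone, such as Anxa1 (2.34 ± 0.39) and the alarmin gene Il33 (1.20 ± 0.21). The median was 1.16 (adjusted p = 6.05e-07, adjusted p = 0.449 with an estimated correlation). Of 21 immediate early genes 7 rose, 11 adjusted over the list alone, led by the transcription factor genes Egr2 (1.92 ± 0.20) and Klf6 (1.25 ± 0.18). The median was 1.01 (adjusted p = 5.93e-05, adjusted p = 0.449 with an estimated correlation). Integrins and basement membrane had 2 of 22 members higher, such as Cd9 (1.28 ± 0.27), against 12 adjusted over the list alone (median 0.81, adjusted p = 0.00207, adjusted p = 0.449 with an estimated correlation). On the same arrays the smooth muscle and enteric neuron lists had medians of 1.57 and 1.80.

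Of 22 macrophage and dendritic cell genes 7 rose, 10 adjusted over the list alone, led by the endotoxin receptor gene Cd14 (2.27 ± 0.21) and Lyz2 (1.77 ± 0.28). The median was 0.57 (adjusted p = 0.000521, adjusted p = 0.449 with an estimated correlation). Of 18 neutrophil genes 3 rose, 5 adjusted over the list alone: the formyl peptide receptor genes Fpr2 (2.79 ± 0.40) and Fpr1 (2.86 ± 0.55), and Mmp8, at least 3.83-fold (adjusted p = 0.0113 for the list, adjusted p = 0.449 with an estimated correlation). Of 11 mast cell genes 2 rose, 6 adjusted over the list alone, namely Hdc (2.83 ± 0.53), which makes histamine, and Gata2 (0.95 ± 0.21), with a list adjusted p = 0.0285 (adjusted p = 0.691 with an estimated correlation). In the list of T and NK cells 10 of 20 members fell, 14 adjusted over the list alone, and 0 rose. The median was -1.38 (adjusted p = 1.38e-07, adjusted p = 0.449 with an estimated correlation). Cd3g and Cd3d, chains of the T cell receptor complex, fell by 3.02 ± 0.30 and 3.28 ± 0.44, and Cd8a was at least 8.2-fold lower. Of 12 B and plasma cell genes 3 fell, 3 also adjusted over the list alone, such as Ms4a1 (-3.42 ± 0.57). The median was -0.89 (adjusted p = 0.0327, adjusted p = 0.449 with an estimated correlation). The mast cell call was lost without wild-type or knockout small intestine replicate 3 (adjusted p up to 0.2505), and the B cell call without knockout replicate 2 or wild-type replicate 3 (up to 0.0818) and with slide row as a block (0.0583). The smooth muscle and enteric neuron medians of 1.57 and 1.80 come from the same arrays.

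Epithelial lists had medians on both sides of 0, and on the same arrays those of the smooth muscle and enteric neuron lists were 1.57 and 1.80. Of 20 genes of the suckling-type enterocyte 3 fell, 5 adjusted over the list alone: Fgf15, the hormone that the ileum sends to the liver (-4.20 ± 0.56), and the urea cycle genes Cps1 (-2.82 ± 0.40) and Otc (-2.96 ± 0.47). The median was -0.81 (adjusted p = 0.00164, adjusted p = 0.618 with an estimated correlation). In the list of fatty acid oxidation and ketogenesis 1 of 22 members fell, against 5 down and 1 up adjusted over the list alone (median -0.79, adjusted p = 0.0192, adjusted p = 0.691 with an estimated correlation). Among 23 brush border genes 0 passed, also adjusted over the list alone. The median was -0.53 (adjusted p = 0.0183, adjusted p = 0.694 with an estimated correlation). Of 22 enteroendocrine genes 7 fell and 2 rose, 10 and 3 adjusted over the list alone. The median was -0.91 (adjusted p = 0.0135, adjusted p = 0.449 with an estimated correlation). Neurog3, the factor that starts the endocrine lineage, fell by 1.96 ± 0.28 and Chga, of the secretory granule, by 1.15 ± 0.18, while the calcium-binding Scgn rose by 1.86 ± 0.28. Of 11 Paneth cell genes 3 rose, 4 adjusted over the list alone, and 0 fell: Pla2g2a, lysozyme gene Lyz1 (3.11 ± 0.27) and the defensin gene Defa29 (4.33 ± 0.65). The median was 1.57 (adjusted p = 0.000109, adjusted p = 0.449 with an estimated correlation). Of 12 tuft cell genes Ptgs1 (1.70 ± 0.36) and the taste-type channel gene Trpm5 (1.62 ± 0.39) rose, 4 adjusted over the list alone (median 0.68, adjusted p = 0.0327, adjusted p = 0.624 with an estimated correlation). In oxidative stress and detoxification 5 of 24 genes fell, 5 down and 1 up adjusted over the list alone, such as the glutathione transferase gene Gstm3 (-3.03 ± 0.27) and the catalase gene Cat (-1.69 ± 0.33). The median was -0.42 (adjusted p = 0.0498, adjusted p = 0.633 with an estimated correlation). Of 30 cell cycle genes 1 fell, Nusap1 (-0.76 ± 0.18), and 0 passed adjusted over the list alone (list adjusted p = 0.0420, adjusted p = 0.739 with an estimated correlation). Of 14 squamous epithelium genes 0 passed, also adjusted over the list alone (median 0.74, adjusted p = 0.0474, adjusted p = 0.524 with an estimated correlation).

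The crypt and junction lists had members on both sides. Of 21 stem cell genes 4 fell, among them Olfm4, Lgr5 and Sox9 (-1.37 ± 0.26), and Lrig1 rose (1.65 ± 0.25), with 6 down and 4 up adjusted over the list alone and a median of -0.04 (adjusted p = 0.504). Of 22 goblet cell genes 2 rose, the lectin gene Zg16 (3.87 ± 0.26) and Retnlb, a secreted resistin-like protein (at least 8.39-fold). In the same list 2 fell, Creb3l4 (-1.29 ± 0.19) and Atoh1, the factor of the secretory lineage (-1.61 ± 0.34), with 2 up and 6 down adjusted over the list alone (median -0.64, adjusted p = 0.098). Among 30 claudin and tight junction genes, which leave out Cldn7, Cldn15 (-2.34 ± 0.24), Cldn14 (-1.49 ± 0.30) and the scaffold gene Tjp3 (-1.10 ± 0.26) fell. Cldn10 (2.12 ± 0.45), Jam2 (1.25 ± 0.21) and Jam3 (1.37 ± 0.30) rose, with the same counts adjusted over the list alone (median -0.40, adjusted p = 0.274).

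The remaining 21 lists did not pass by camera in the small intestine (adjusted p = 0.149 to 0.990), with 0 to 4 members higher and 0 to 3 lower in each, and 0 to 6 higher and 0 to 4 lower adjusted over the list alone. Medians and adjusted p were -0.14 and 0.671 for Wnt targets, 0.21 and 0.274 for the Notch pathway, -0.36 and 0.990 for the adult-type enterocyte, -0.29 and 0.438 for lipid absorption, and -0.02 and 0.990 for cholesterol synthesis. They were -0.50 and 0.438 for the colon region, -0.60 and 0.149 for the small intestine region, -0.38 and 0.167 for ion transport, and -0.27 and 0.427 for adherens junctions. The interferon list had -0.06 and 0.676, the unfolded protein response -0.22 and 0.533, and p53 targets -0.04 and 0.654. Values were, for hypoxia and glycolysis 0.00 (just below 0) and 0.572, glucocorticoid response 0.33 and 0.235, the circadian clock -0.08 and 0.676, and amino acid starvation -0.12 and 0.377. By fry the glucocorticoid list passed, with an adjusted p of 0.0479 here and 0.0219 over both segments (0.0574 there by camera). Among other cell types, erythroid cells had 0.30 and 0.808, pancreatic acinar cells 0.16 and 0.572, and hepatocytes -0.81 and 0.676. The sex-linked list had -2.26 and 0.438, and the chromosomal neighbours of Cldn7 had 0.01 and 0.320. For the interferon, p53 and hypoxia lists the median lay below 0 with mean and test above, and for the pancreatic list the mean lay below 0 with median and test above.

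The count in the small intestine depended on single arrays. It was 70 without knockout small intestine replicate 3, 71 without wild-type small intestine replicate 3, 105 without wild-type large intestine replicate 2 or 3, 779 without knockout large intestine replicate 2 or 3, and 3827 without knockout small intestine replicate 2. It was 1145 with slide row as a block, 488 without a background filter, and 14 without both knockout arrays numbered 3, an alternative chosen after seeing the data. The balance turned with some of these: 27 genes were higher and 43 lower without knockout small intestine replicate 3, and 32 and 39 without wild-type small intestine replicate 3. It was 48 higher and 57 lower without either wild-type large intestine array, and 15 and 20 with the 2 compared groups alone. Some lists kept their call with medians over fits without 1 array of 0.91 to 2.18 (smooth muscle), 0.60 to 1.53 (antimicrobial), 1.19 to 2.40 (Paneth cell), 0.54 to 1.08 (neutrophil, 0.95 with all arrays), 0.37 to 0.76 (macrophage), 0.26 to 0.59 (endothelium) and 0.66 to 1.17 (adipocyte). Of 103 named genes that passed, 4 still passed without both knockout arrays numbered 3, 12 with the 2 compared groups alone, 15 without wild-type small intestine replicate 3, 17 without knockout small intestine replicate 3, 23 without either wild-type large intestine array and 78 with slide row as a block, and 0 turned direction. Besides the mast and B cell lists, 7 lists lost their call when 1 array was left out. These were tuft cell and brush border without wild-type or knockout replicate 3 (adjusted p up to 0.213 and 0.786) and suckling-type enterocyte without knockout replicate 3 (0.129). The others were fatty acid oxidation without wild-type replicate 2 or knockout replicate 3 (up to 0.116), and cell cycle, oxidative stress and squamous epithelium in 5, 6 and 4 of the 8 such fits (up to 0.971, 0.196 and 0.2505). Oxidative stress also lost it with slide row as a block (0.0814).

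**Figure D2:**
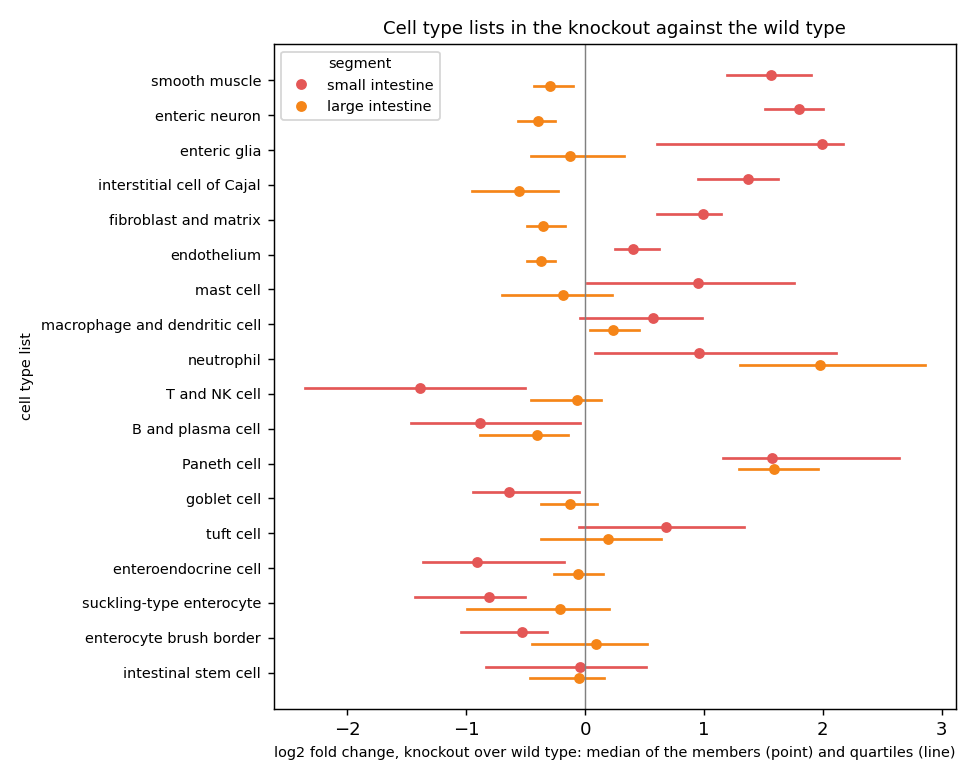
Log2 fold change, knockout over wild type, of 18 cell type lists (vertical axis), in the small and in the large intestine (horizontal axis), with a point at the median of each list's measured genes and a line from the lower to the upper quartile. In the small intestine the enteric neuron list has a median of 1.80 and the T and NK cell list a median of -1.38.

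In the large intestine, 33 genes were higher in the knockout, Sprr2k and Retnlb among them, and 29 were lower, among them Muc5b. The lists of antimicrobial, inflammatory and neutrophil genes shifted up (adjusted p = 0.518 with an estimated correlation for each of the 3, so that these calls are lost). Sprr2k, a small proline-rich protein of the cornified envelope family, was at least 28.1-fold higher (adjusted p = 0.00382), and Retnlb rose by 3.98 ± 0.44 (adjusted p = 0.0338). Muc5b, a gel-forming mucin, fell by 3.5998 ± 0.21 (adjusted p = 0.00382), and Nlrp1b, an inflammasome sensor, fell by 3.18 ± 0.18 (adjusted p = 0.00382). Of 20001 genes 62 passed.

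Other large rises were Clca4c-ps (5.56 ± 0.62) and Clca4a (4.57 ± 0.44), of the chloride channel accessory family, the macrophage scavenger receptor gene Marco (4.54 ± 0.54), the acute-phase glycoprotein gene Lrg1 (4.23 ± 0.38) and Sprr1a (4.05 ± 0.49), with adjusted p between 0.0254 and 0.0391. Bounds were at least 15.5-fold for Pla2g2a (adjusted p = 0.0254), at least 10-fold for Sprr2d (0.0487) and at least 7.83-fold for Slc25a48 (0.0424), a mitochondrial carrier. The largest falls were Klk15, a kallikrein-type protease (-5.44 ± 0.37, adjusted p = 0.00711), Mcoln3, a cation channel of endosomes and lysosomes (-5.10 ± 0.52, adjusted p = 0.0304), and Mamdc4, the apical endosomal glycoprotein of suckling enterocytes (-4.63 ± 0.43, adjusted p = 0.0254). Pramel34 (-3.13 ± 0.32) and Apoa4, an apolipoprotein of chylomicrons (-2.80 ± 0.27), also fell, but with outlier flags ignored another probe stood for Pramel34, at 0.90 and not past the threshold. Bsnd, a chloride channel subunit, was at least 6.06-fold lower, Kcnh6, a potassium channel, at least 2.51-fold and Mrps36-ps1 at least 2.31-fold (adjusted p = 0.0338 to 0.0425). Clca4c-ps was well above background on 1 of the 2 wild-type arrays. On knockout large intestine replicate 2, liver transcripts were high: Hp, the haptoglobin gene, read 4.30 on that array and 1.94 on replicate 3, while Lrg1 read -0.40 and 0.03.

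Of the 51 lists 18 passed in the large intestine, 14 up and 4 down, while camera with an estimated correlation gave 0 (4 at an unadjusted p under 0.05) and fry 0 (13 at an unadjusted p under 0.05). Of 23 antimicrobial genes 2 rose, Retnlb and Sprr1a, against 9 adjusted over the list alone, and the bacterial siderophore-binding Lcn2 had 2.77 ± 0.45 (adjusted p = 0.0931). The median was 1.46 (adjusted p = 3.38e-10). Of 27 inflammatory genes 0 passed, against 14 up adjusted over the list alone, with Cxcl5 at 3.58 ± 0.53 (adjusted p = 0.07) and Cxcl1 at 2.77 ± 0.46 (adjusted p = 0.0968). The median was 0.94 (adjusted p = 3.89e-10). Of 18 neutrophil genes Ly6g rose (3.67 ± 0.34), against 8 adjusted over the list alone. The median was 1.97 (adjusted p = 2.2e-07). Of 11 Paneth cell genes Pla2g2a rose, against 2 adjusted over the list alone (median 1.59, adjusted p = 1.76e-05, adjusted p = 0.616 with an estimated correlation). The repair and fetal-type program had 1 of 23 members higher, Sprr1a, against 5 adjusted over the list alone, with Ly6a at 3.02 ± 0.46 (adjusted p = 0.0786) and a median of 0.67 (adjusted p = 0.000683, adjusted p = 0.616 with an estimated correlation). Of 22 macrophage genes 0 passed, against 2 up adjusted over the list alone (median 0.24, adjusted p = 0.00948, adjusted p = 0.616 with an estimated correlation). On the hepatocyte list, whose median was 5.31 above the genes' means on knockout replicate 2 alone and between -1.25 and -0.27 on the other 7 arrays, 0 of 15 genes passed, also adjusted over the list alone (median 2.65, adjusted p = 0.00459, adjusted p = 0.692 with an estimated correlation). Without that array its median was -0.47, and it did not pass.

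Other shifts made up the rest of the lists that passed in the large intestine, and 0 of their genes passed over all genes. The shift was up for cell cycle (30 genes, median 0.27, adjusted p = 0.000333, adjusted p = 0.622 with an estimated correlation) and for cholesterol synthesis (22 genes, median 0.52, adjusted p = 9.36e-05, adjusted p = 0.622 with an estimated correlation). It was also up for adherens junctions (19 genes, median 0.37, adjusted p = 0.00459, adjusted p = 0.622 with an estimated correlation) and for oxidative stress (24 genes, median 0.35, adjusted p = 0.00459, adjusted p = 0.622 with an estimated correlation). The lists of ion transport (24 genes, median 0.44, adjusted p = 0.0184, adjusted p = 0.518 with an estimated correlation), hypoxia (24 genes, median 0.20, adjusted p = 0.0387, adjusted p = 0.616 with an estimated correlation) and the unfolded protein response (23 genes, median 0.25, adjusted p = 0.0385, adjusted p = 0.622 with an estimated correlation) shifted up as well. Down were fibroblast and matrix (22 genes, median -0.36, adjusted p = 0.00398) and endothelium (18 genes, -0.37, 0.000783). So were the Notch pathway (18 genes, -0.40, 0.0133) and enteric neurons (18 genes, -0.40, 0.0387). With an estimated correlation the adjusted p of these lists, in order, was 0.652, 0.622, 0.601 and 0.795. Adjusted over the list alone, 1 ion transport gene was higher and 0 genes of the other 10 of these lists passed.

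Stem cell, goblet, claudin and metalloproteinase lists did not pass in the large intestine. Of 21 stem cell genes Olfm4 rose, at least 1.3-fold (adjusted p = 0.0254), being well above background on 1 of the 2 knockout arrays and neither wild-type array. Lgr5 had -1.29 ± 0.27 (adjusted p = 0.158), with 1 up and 1 down adjusted over the list alone and a median of -0.05 (adjusted p = 0.736). Of 22 goblet cell genes Retnlb rose, the same count adjusted over the list alone (median -0.13, adjusted p = 0.602). Of 20 metalloproteinases and inhibitors Mmp10 rose (3.54 ± 0.46, adjusted p = 0.048), against 2 adjusted over the list alone (median 0.15, adjusted p = 0.136). Of 30 claudin and tight junction genes 0 passed, also adjusted over the list alone (median 0.25, adjusted p = 0.051). The smooth muscle list had a median of -0.30 (adjusted p = 0.183) and the T and NK cell list -0.07 (adjusted p = 0.692). The goblet list's mean lay above 0 with median and test below, the brush border mean below with median and test above, the small intestine region median above with mean and test below, and the enteric glia median below with mean and test above.

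The count in the large intestine was 0 without wild-type large intestine replicate 2 or 3, where 1696 and 1181 genes had an unadjusted p under 0.05 in limma, and 22 without knockout large intestine replicate 2. It was 100 without both knockout arrays numbered 3, and 32 with probes above background on all arrays. The balance moved too: 73 genes were higher and 13 lower without knockout large intestine replicate 3, 78 and 22 without both knockout arrays numbered 3, and 22 and 39 without either wild-type small intestine array. It was 55 and 66 with the 2 compared groups alone, 9 and 10 without a background filter, and 5 and 10 with slide row as a block. Medians over the fits without 1 array ran from 1.05 to 2.60 for the Paneth cell and 1.01 to 2.25 for the antimicrobial list, which kept their calls. Of 23 named genes that passed, 0 still passed without either wild-type array, 10 without knockout replicate 2 and 7 with slide row as a block, where Retnlb had an adjusted p of 0.0656 and the enteric neuron list one of 0.0613. Leaving out knockout large intestine replicate 3 ended the calls of ion transport, adherens junctions, oxidative stress, fibroblast and matrix, hypoxia, unfolded protein response and enteric neurons (adjusted p up to 0.399 over the fits without 1 array). Without wild-type replicate 2 the Notch, hypoxia and neuron calls ended, and the unfolded protein response call also ended without wild-type replicate 3 or either knockout small intestine array.

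Both segments were fitted with the segment as a term (n = 4 arrays per genotype, which may not come from 4 pups). The lists of inflammatory, antimicrobial, neutrophil and macrophage genes shifted up in the knockout. Those of suckling-type enterocytes and T and NK cells (median -1.38 in the small and -0.07 in the large intestine) shifted down. With an estimated correlation these calls are lost (in that order adjusted p = 0.143, 0.143, 0.151, 0.344, 0.577 and 0.660). Marco rose by 4.80 ± 0.38 (adjusted p = 0.00979) and Lrg1 by 3.72 ± 0.32 (adjusted p = 0.0107). Fgf15 fell by 3.64 ± 0.43 (adjusted p = 0.0274), and Lgr5 by 1.75 ± 0.25 (adjusted p = 0.045). In total 126 genes passed, 79 higher and 47 lower.

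The other large rises over both segments were Hp (5.06 ± 0.73), Gml (4.62 ± 0.53) and Slc13a3 (4.49 ± 0.58), with adjusted p of 0.0261 to 0.045, and at least 19.6-fold for Clec4e (0.0243), 16.2-fold for Pla2g2a (0.00979) and 8.29-fold for the chemokine gene Cxcl2 (0.0394). The other large falls were Il22ra2 (-4.62 ± 0.68), Mcoln3 (-3.85 ± 0.58), Pramel34 (-3.85 ± 0.35; 0.51 and not passed with outlier flags ignored), the antisense transcript Tnfsf13os (-3.42 ± 0.36), the carboxylesterase gene Ces1c (-2.85 ± 0.29) and the prostaglandin D2 receptor gene Ptgdr (-1.96 ± 0.23). They had adjusted p of 0.0131 to 0.0472. Defb29, a beta-defensin, was at least 4.23-fold lower (adjusted p = 0.00993). Retnlb (adjusted p = 0.00979), Mmp8 (0.0424) and Anxa10 (0.049) rose, but with neither wild-type array of 1 segment well above background (small intestine, for Anxa10 large), so that their sizes over both are not measured. Fgf15 and Ptgdr were well above background on 3 of the 4 knockout arrays. Hp read highest on knockout large intestine replicate 2, the array with high liver transcripts.

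Of 51 lists 19 passed over both segments, 15 up and 4 down; camera with an estimated correlation gave 0 (7 at an unadjusted p under 0.05), and fry gave 8. Of 27 inflammatory genes 6 rose, 13 adjusted over the list alone, among them Cxcl5 (3.51 ± 0.36), Cxcl1 (2.84 ± 0.31) and Ccl7 (2.66 ± 0.33). The median was 0.81 (adjusted p = 3.42e-11, adjusted p = 0.143 with an estimated correlation). Of 23 antimicrobial genes Retnlb and Sprr1a (3.599 ± 0.37) rose, 14 adjusted over the list alone (median 1.47, adjusted p = 1.85e-10, adjusted p = 0.143 with an estimated correlation). The repair list had 1 of 23 members higher, 12 adjusted over the list alone (median 0.86, adjusted p = 8.55e-10, adjusted p = 0.143 with an estimated correlation). Of 18 neutrophil genes Fpr2 (2.42 ± 0.31), Fpr1 (2.64 ± 0.38) and Mmp8 rose, 7 adjusted over the list alone (median 1.52, adjusted p = 2.02e-07, adjusted p = 0.151 with an estimated correlation). Of 22 macrophage genes Lyz2 rose (1.70 ± 0.19), 8 adjusted over the list alone (median 0.43, adjusted p = 2.03e-05, adjusted p = 0.344 with an estimated correlation). Of 22 integrin and basement membrane genes 1 rose, also adjusted over the list alone (median 0.45, adjusted p = 0.00031, adjusted p = 0.143 with an estimated correlation). Of 20 metalloproteinases and inhibitors Mmp8 rose, 7 adjusted over the list alone (median 0.44, adjusted p = 1.11e-06, adjusted p = 0.382 with an estimated correlation). Of 11 Paneth cell genes Pla2g2a rose, 7 adjusted over the list alone (median 1.74, adjusted p = 1.67e-08, adjusted p = 0.319 with an estimated correlation).

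The other lists that shifted up over both segments had 0 members past the threshold over all genes. They were immediate early genes (4 of 21 adjusted over the list alone, median 0.52, adjusted p = 0.000198). Tuft cell was another (2 of 12, median 0.47, adjusted p = 0.0306). With 0 adjusted over the list alone, they were also cholesterol synthesis (median 0.28, adjusted p = 0.0120) and smooth muscle (0.61, 0.00031). The same holds for fibroblast and matrix (0.30, 0.0229), enteric neuron (0.70, 0.00392) and enteric glia (0.78, 0.0118). With an estimated correlation the adjusted p of these lists, in order, was 0.478, 0.577, 0.772, 0.748, 0.772, 0.772 and 0.577. In the large intestine alone, the fibroblast and neuron lists passed downward (medians -0.36 and -0.40), and smooth muscle had -0.30. The rise of these lists came from the small intestine (0.996, 1.80 and 1.57). Down were suckling-type enterocytes (Fgf15 fell, 4 of 20 adjusted over the list alone, median -0.81, adjusted p = 0.00031). So were T and NK cells (0 of 20 members, 6 adjusted over the list alone, median -0.75, adjusted p = 6.58e-05). The lists of B and plasma cells (0 of 12, median -0.63, adjusted p = 0.0114) and enteroendocrine cells (0 of 22, -0.52, 0.0486) shifted down too. Both also had 0 members adjusted over the list alone. With an estimated correlation the adjusted p of these lists, in order, was 0.577, 0.660, 0.394 and 0.553. In the large intestine the enteroendocrine median was -0.06 (adjusted p = 0.898). The stem cell list, in which Lgr5 fell (1 of 21 genes, 4 adjusted over the list alone), had an adjusted p of 0.488, the goblet list 0.0574 with Retnlb higher (2 up and 4 down adjusted over the list alone), and the claudin list 0.749 with 0 of 30. The median lay below 0 with mean and test above for the colon region, median and mean lay below with the test above for ion transport, claudins, oxidative stress and pancreatic acinar cells, and the amino acid starvation mean lay below with median and test above.

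The count over both segments was 18 without wild-type small intestine replicate 2 or knockout large intestine replicate 3, 56 without knockout small intestine replicate 2, 54 without knockout large intestine replicate 2, 65 without wild-type small intestine replicate 3, and 39 without knockout small intestine replicate 3. Without wild-type large intestine replicate 2 it was 3, without replicate 3 it was 1, and without both knockout arrays numbered 3 it was 5. It was 66 with slide row as a block (Lgr5 had an adjusted p of 0.0715) and 53 without a background filter. Of 30 named genes that passed, 2 still passed without wild-type large intestine replicate 2, 0 without replicate 3, 1 without both knockout arrays numbered 3 and 19 with slide row as a block. Leaving out wild-type or knockout small intestine replicate 3 ended the calls of fibroblast, neuron, glia, tuft and enteroendocrine lists (adjusted p up to 0.647; enteroendocrine 0.0563 with slide row as a block), and smooth muscle lost its call without the wild-type one (0.0762). The fibroblast and enteroendocrine calls also ended without either small intestine replicate 2, the tuft and enteroendocrine calls without knockout large intestine replicate 2, and cholesterol synthesis without wild-type small intestine replicate 2 or either large intestine replicate 3 (up to 0.193). The balance was 30 higher and 35 lower without wild-type small intestine replicate 3, 9 and 9 without knockout large intestine replicate 3, 350 and 430 with an animal block taken from the numbers, and 346 and 337 with the average of the 4-group contrasts. With normexp background correction 76.2% of the genes that passed were higher, against 62.7%. Some lists kept their call with medians over fits without 1 array of 0.85 to 1.84 (neutrophil), -0.97 to -0.37 (suckling-type enterocyte), 0.24 to 0.51 (integrins), 0.34 to 0.77 (metalloproteinases), 0.25 to 0.64 (immediate early), -0.99 to -0.48 (T and NK cell) and -0.80 to -0.40 (B cell).

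Some genes passed in both segments. Both share each gene's spread estimate, so the expected overlaps and their p-values are only a rough guide. Of the genes that rose, 14 rose in both segments, against 2.14 for independent lists (odds ratio 10.75, Fisher's exact test, two-sided, p = 5.42e-09, adjusted p = 1.08e-08 over 2 tests): C4b, Clca4a, Clca4c-ps, Cstdc5, Krt20, Lrg1, Marco, Mmp10, Pla2g2a, Ren1, Retnlb, Serpina3f, Slc25a48 and Sprr1a. Of those that fell, 9 fell in both, against 1.03 (odds ratio 12.3, exact p = 4.56e-07, adjusted p = 4.56e-07). Among them were the targeted Cldn7, Defb29, Mcoln3, Muc5b, Nlrp1b and Pramel34 (not in both with outlier flags ignored). In opposite directions 4 genes passed. Across all 20001 genes the segments' fold changes had a Pearson r of 0.12 and a Spearman rho of -0.04 (genes are not independent). Leaving out 1 array gave an r of 0.0408 to 0.194, and without either wild-type large intestine array 0 genes passed there, so that no overlap was left. Of the 2006 genes that passed in the small intestine, 919 (45.8%) had the same sign in the large.

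The difference between segments was tested as the knockout effect in the large minus that in the small intestine. Gasdermin C genes differed, by 7.32 ± 0.65 for Gsdmc4 (adjusted p = 0.0242; -6.58 in the small and 0.74 in the large intestine) and by 7.01 ± 0.79 for Gsdmc3 (adjusted p = 0.048; -6.82 and 0.20). Olfm4 passed as well (adjusted p = 0.00184), but its wild-type large intestine arrays lay below background, so that the size of its difference is not measured. In total 28 genes passed, 19 with the higher and 9 with the lower knockout effect in the large intestine. Downward were the major urinary protein gene Mup20 (-5.24 ± 0.29; 4.27 in the small and -0.96 in the large intestine), Ttll9 (-4.04 ± 0.32; 1.504 and -2.54) and Zg16 (-3.35 ± 0.37; 3.87 and 0.52), with adjusted p of 0.00642 to 0.0444. Sprr2k and Gsdmcl-ps also passed upward and Klk15 and Crisp3 downward (adjusted p = 0.00746 to 0.0355). They rest on 1 or more groups below background, so their sizes are not measured. Mup20 was well above background on 1 of the 2 wild-type small intestine arrays and Ttll9 on 1 of the 2 knockout ones. The count was 1 without wild-type small intestine replicate 3 or either wild-type large intestine array, 10 without knockout small intestine replicate 3, and 15 without knockout large intestine replicate 2. It was 43 without wild-type small intestine replicate 2, 53 without knockout large intestine replicate 3 and 986 without knockout small intestine replicate 2. With slide row as a block 5 of the 10 named genes still passed, without Gsdmc4 (0.0553) and Gsdmc3 (0.0986), and the count was 5 with probes above background on all arrays and 15 without a filter. The share with the higher effect in the large intestine was 67.9%, against 52% with quantile normalization and 57.6% with the deposited normalized table.

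The wild-type arrays give the baseline difference between large and small intestine. The list of goblet cell genes shifted up and that of lipid absorption down in the large intestine. With an estimated correlation even these calls are lost (adjusted p = 0.345 and 0.410). Hoxb13 and Hoxa11, transcription factors of the posterior body axis, were at least 5055-fold and at least 631-fold higher in the large intestine, and Hoxd13 by 9.72 ± 0.54. Gip, an incretin hormone of the upper small intestine, was at least 1135-fold lower, and Lct, the lactase of suckling pups, had a log2 difference of -10.15 ± 0.66. In all 3991 genes passed, 1997 higher and 1994 lower in the large intestine.

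Among the largest differences on the large intestine's side were Fxyd4, a regulator of the sodium pump (at least 1202-fold), Retnlb (at least 418-fold), Vsig1 (at least 578-fold), Saa2 (10.95 ± 0.43), Cyp2d34 (9.85 ± 0.25) and the amino acid transporter gene Slc6a14 (9.50 ± 2.15), with adjusted p of 2.35e-05 to 0.0272. On the small intestine's side were Cfi (at least 539-fold lower), Olfm4 (at least 192-fold lower), the glucose transporter gene Slc2a2 (-10.43 ± 2.03), Leap2 (-9.65 ± 1.53) and the fatty acid-binding Fabp1 (-8.76 ± 1.63), with adjusted p of 2.35e-05 to 0.025. Hoxd13 and Slc6a14 were well above background on 1 of the 2 wild-type small intestine arrays.

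Of the lists 24 passed in wild type, 12 up and 12 down in the large intestine, against 0 by camera with an estimated correlation (6 at an unadjusted p under 0.05) and 19 by fry. The goblet cell list shifted up (19 of 22 higher, 20 adjusted over the list alone; Zg16 by 5.48 ± 0.26, Klk1 by 6.01 ± 0.33; adjusted p = 3.12e-13, adjusted p = 0.345 with an estimated correlation). The lipid absorption list shifted down (21 of 22 lower, also adjusted over the list alone; Apob by -6.84 ± 0.32 and Apoc3 by -6.04 ± 0.25; adjusted p = 1e-14, adjusted p = 0.410 with an estimated correlation). So did the suckling-type enterocyte list (19 of 20, also adjusted over the list alone; Apoa4 by -5.96 ± 0.27; adjusted p = 2.35e-13, adjusted p = 0.378 with an estimated correlation). The colon region list was up (12 up and 2 down of 20, 12 and 4 adjusted over the list alone; adjusted p = 1.45e-07, adjusted p = 0.345 with an estimated correlation). The small intestine region list was down (16 down and 1 up of 22, 17 and 1 adjusted over the list alone; adjusted p = 8.57e-10, adjusted p = 0.345 with an estimated correlation). The Paneth cell list shifted down (7 of 11 lower, 8 down and 1 up adjusted over the list alone; Defa5 by -7.87 ± 0.66; adjusted p = 3.49e-05, adjusted p = 0.536 with an estimated correlation). The brush border list did too (17 of 23, 18 down and 1 up adjusted over the list alone; adjusted p = 4.43e-08, adjusted p = 0.604 with an estimated correlation). The smooth muscle list shifted up (7 of 18 higher, 9 adjusted over the list alone; adjusted p = 5.15e-05, adjusted p = 0.612 with an estimated correlation), while wild-type small intestine replicate 3 had the lowest smooth muscle list of the 8 arrays.

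The other 16 lists that passed are given with their medians. Higher in the wild-type large intestine were cholesterol synthesis (9 of 22 higher, 13 adjusted over the list alone; median 1.17, adjusted p = 7.13e-05, adjusted p = 0.616 with an estimated correlation) and hypoxia and glycolysis (13 of 24, 14 up and 1 down adjusted over the list alone; 0.97, adjusted p = 9.32e-05, adjusted p = 0.345 with an estimated correlation). The same holds for enteric neuron (5 of 18, 10 adjusted over the list alone; 1.32, adjusted p = 0.00016, adjusted p = 0.616 with an estimated correlation), fibroblast and matrix (5 of 22, 6 adjusted over the list alone; 0.56, adjusted p = 0.00576, adjusted p = 0.664 with an estimated correlation) and cells of Cajal (4 up and 1 down of 8, 6 and 1 adjusted over the list alone; 1.22, adjusted p = 0.0106, adjusted p = 0.604 with an estimated correlation). So were ion transport (9 up and 3 down of 24, 13 and 3 adjusted over the list alone; 0.69, adjusted p = 0.0116, adjusted p = 0.345 with an estimated correlation), antimicrobial defence (8 up and 3 down of 23, 9 and 3 adjusted over the list alone; 0.70, adjusted p = 0.0216, adjusted p = 0.612 with an estimated correlation) and immediate early genes (5 up and 1 down of 21, 6 and 1 adjusted over the list alone; 0.35, adjusted p = 0.0202, adjusted p = 0.604 with an estimated correlation). The pancreatic acinar list was higher too (4 of 19, 5 adjusted over the list alone; 2.30, adjusted p = 0.00276, adjusted p = 0.652 with an estimated correlation), with wild-type large intestine replicate 2 at 2.13 and replicate 3 at 0.17 over the genes' means, and it did not pass without replicate 2 (0.0995). Lower were the interferon list (12 of 28 lower, 15 down and 1 up adjusted over the list alone; -1.36, adjusted p = 9.4e-05, adjusted p = 0.643 with an estimated correlation), fatty acid oxidation (8 of 22, 9 adjusted over the list alone; -1.15, adjusted p = 0.000214, adjusted p = 0.612 with an estimated correlation), enteroendocrine (11 down and 2 up of 22, 11 and 3 adjusted over the list alone; -0.88, adjusted p = 0.0189, adjusted p = 0.345 with an estimated correlation) and adult-type enterocyte (6 down and 2 up of 12, also adjusted over the list alone; -2.24, adjusted p = 0.029, adjusted p = 0.536 with an estimated correlation). So were macrophages (4 down and 1 up of 22, 7 and 1 adjusted over the list alone; -0.45, adjusted p = 0.0354, adjusted p = 0.604 with an estimated correlation), amino acid starvation (8 down and 1 up of 20, 10 and 2 adjusted over the list alone; -0.69, adjusted p = 0.0411, adjusted p = 0.530 with an estimated correlation) and endothelium (1 down of 18, 0 adjusted over the list alone; -0.23, adjusted p = 0.0465, adjusted p = 0.650 with an estimated correlation). Besides the pancreatic one, 5 calls ended in fits without 1 array: antimicrobial defence without wild-type large intestine replicate 2 (0.0708), immediate early genes without wild-type small intestine replicate 2 or large intestine replicate 3, and amino acid starvation without either wild-type replicate 3 and with slide row as a block (0.0749). The others were macrophages without either wild-type replicate 2, and endothelium without either wild-type replicate 2 or either knockout small intestine array. Some lists kept their call with medians over these fits of 0.72 to 1.59 (cholesterol synthesis), 0.72 to 1.82 (smooth muscle, 1.24 with all arrays), 0.36 to 0.74 (fibroblast) and 0.79 to 1.91 (enteric neuron). Stem cell and Wnt medians lay above 0 with mean and test below, the adherens junction mean lay above 0 with median and test below, inflammatory and circadian means lay below 0 with median and test above, and the mast cell median lay below 0 with mean and test above.

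The wild-type count was 903 without wild-type large intestine replicate 2, 953 without replicate 3 and 1669 without wild-type small intestine replicate 3. In the knockout, 3207 genes passed between large and small intestine, 1678 higher and 1529 lower in the large, and leaving out 1 array gave 1202 (without knockout large intestine replicate 3) to 3073. It was 1889 without either wild-type large intestine array and 1895 without knockout large intestine replicate 2.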

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

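The tests of the epithelium share, of the outer wall and of the splits with both segments on each side, and the bound on posterior Hox genes named below, were chosen only after the result was seen.

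The knockout effect differed between the segments for 28 genes, by the test of the difference itself (large minus small intestine, log2 scale). The named ones were Olfm4 (7.56), Gsdmc4 (7.32), Gsdmc3 (7.01), Sprr2k (6.72) and Gsdmcl-ps (5.51) upward, and Klk15 (-5.65), Mup20 (-5.24), Crisp3 (-4.25), Ttll9 (-4.04) and Zg16 (-3.35) downward. These are the tested values; Olfm4, Sprr2k, Gsdmcl-ps, Klk15 and Crisp3 rest on groups below background, so their sizes are not measured. Over both segments 126 genes passed in the real grouping. Of the 34 splits of the 8 arrays into 4 and 4 that could be fitted, 1 gave as many, the real one, and the highest other gave 1, but 16 of these splits set 3 arrays of a segment against 1 and so overlap the segment term. The 18 splits with 2 arrays of each segment on each side are too few for a share under 0.05 (real 126, highest other 1).

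In the knockout small intestine the lists of smooth muscle, enteric neurons, glia and cells of Cajal shifted up and those of lymphocytes down, calls that are lost with an estimated correlation (adjusted p = 0.449 for each). A smaller share of epithelium stays open. The T and NK cell list (median -1.38, upper quartile -0.50, 0 of 20 above 0) cannot test it. Its fall is part of the pattern, and such cells may lie in the epithelium. For the 4 rises, more outer wall (muscle layer and nerve plexus) in the knockout samples stays open. These also moved together between the 2 wild-type arrays, by 0.63 to 1.14 (at least 0.596 over all genes' median). T and NK cells moved by -0.108 and B cells by -0.307 there, short of their knockout falls. Wall may vary with the sample, and slide column, which follows the group, cannot be told apart from it. The genotype stays open as untested.

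Anxa10, Tmprss15 and Pdx1, genes of the stomach and duodenum, rose in the knockout small intestine while Fgf15, a gene of the ileum, fell (Vsig1 rose too, but in wild type it was at least 578-fold higher in the large than in the small intestine and so does not point to the stomach here), so the knockout samples could have been cut nearer the stomach. With these genes left out, a list of upper small intestine genes had a median of -0.35 (4 of 14 above 0, and the 1 member that passed, S100g, fell by 3.98, which goes against such a cut) and a list of lower ones -0.69 (1 of 11 above 0), a difference of 0.34, with an adjusted p in limma's camera of 0.132 for both over 3 lists. The posterior Hox genes had a median of 0.86 (11 of 13 above 0, camera adjusted p = 0.0999, under 0.05 unadjusted, adjusted p = 0.587 with an estimated correlation). By the bound fixed before the result was seen, under which an unadjusted upward shift of these genes excludes the explanation, it was excluded, but that bound was amended after the result was seen, because posterior Hox genes are expressed in the mesenchyme of the gut wall and the fibroblast and matrix list itself shifted by 0.996, more than the Hox genes. Under the amended bound a cut nearer the stomach cannot be told apart from the genotype, which stays open as untested.

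Some genes near Cldn7 on chromosome 11 passed over both segments, among them Elp5, whose probe lies next to that of Cldn7 (0.93), Tnfsf13os (-3.42) and Eno3 (1.18), so a chromosome segment that differs between the knockout and wild-type mice is a candidate explanation. Within 10 Mb of the Cldn7 probe 4 of 367 genes passed (1.09%, against 0.613% elsewhere), an odds ratio of 1.79 (95% confidence interval 0.477 to 4.74, two-sided Fisher's exact p = 0.294, adjusted p = 0.464 over 12 tests of windows and comparisons). Within 2 Mb the odds ratio was 3.97 (3 of 126 genes, exact p = 0.0440, adjusted p = 0.228), and within 10 Mb it was 0.945 in the small intestine, while in the large intestine Nlrp1b (-3.18) and Nlrp1c-ps (-1.57) passed, 1.19 and 1.27 Mb from the probe. Within 20 Mb, 10 of 662 genes passed (odds ratio 2.58, exact p = 0.00834, adjusted p = 0.100). The counts are too few to decide, and the genotype itself stays open as untested.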

How the results depend on the processing

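The alternative without both knockout arrays numbered 3 was chosen after the result was seen, and the others were fixed before. Where 1 array is left out, the lone array of its group is assumed to vary like the other groups. Counts are genes past an adjusted p of 0.05 in limma, and the cause of a change was not tested unless the setting's construction shows it.

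Leaving out each array in turn gave 70 to 3827 genes in the small intestine, 0 to 86 in the large intestine, 1 to 65 over both segments, 1 to 986 for the difference between segments, 903 to 4976 between wild-type segments and 1202 to 3073 between knockout segments. Cldn7 kept its direction, at -4.97 to -3.70 in the small intestine, -3.58 to -3.45 in the large and -4.10 to -3.59 over both. The correlation between segments ran from 0.0408 to 0.194. List calls numbered 22 to 27, 13 to 23, 13 to 23 and 21 to 25 in the order small intestine, large intestine, both segments and wild-type segments.

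Without a background filter, which adds genes to the adjustment, 488 genes passed in the small intestine, 19 in the large, 53 over both and 15 for the difference, and Cldn7 in the large intestine (-3.52) had an adjusted p of 0.0570, within 0.00816 to 0.300 over its alternatives. With only probes well above background on all arrays, 32 passed in the large intestine and 5 for the difference, and named genes below background on any array gave no value. With the replicate block, which is also a slide row block because each number filled 1 row, the counts were 1145, 15 (5 higher and 10 lower) and 66 (small, large, both), and Cldn7 in the large intestine (-3.52) had an adjusted p of 0.0719. Deviations of the replicates correlated at 0.00865 to 0.263 across genes between groups. With the 2 compared groups alone, which leaves 2 residual degrees of freedom, the counts were 35, 121 and, between knockout segments, 1583, and Cldn7 in the small intestine (-4.34) had an adjusted p of 0.0764, within 0.00299 to 0.0764. Over both segments 780 genes passed with an animal block (350 higher and 430 lower) and 683 with the average of the 4-group contrasts.

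Without both knockout arrays numbered 3, 14 genes passed in the small intestine, 100 in the large, 5 over both, 11 for the difference and 1660 between knockout segments, and the correlation between segments was 0.176. Both arrays read as female, and whether sex is the cause was not tested. List calls with an estimated correlation were 0, 0, 0 and 0 (4, 4, 7 and 6 at an unadjusted p under 0.05), and fry gave 9, 0 (13 unadjusted) and 8 in the knockout comparisons.

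No named gene that passed turned direction, apart from Pramel34 with outlier flags ignored, where another probe stood for the gene (0.90 in the large intestine, 0.51 over both). The turned directions were otherwise in lists, with medians near 0 apart from the hepatocyte list (2.65). The stem cell test between wild-type segments turned with normexp (median 0.0178), no filter (0.11), all arrays above background (0.12), the replicate block (0.11), both knockout arrays numbered 3 dropped (0.11), and without knockout small intestine replicate 2 (0.11) or 3 (0.11), wild-type small intestine replicate 3 (0.13) and wild-type large intestine replicate 3 (0.07). It also turned in the small intestine without knockout replicate 2 (0.0036), and in the large intestine without wild-type replicate 2 (-0.0211) and by fry (-0.0508). The goblet test turned in the large intestine without wild-type replicate 2 (-0.0376), the hepatocyte test there without knockout replicate 2 (-0.47), and the claudin test between wild-type segments without wild-type small intestine replicate 3 (-0.0222) and over both segments without wild-type (-0.081) or knockout (-0.15) large intestine replicate 3 and by fry (-0.0527). The causes were not tested. With each array left out, these medians ran from -0.285 to 0.0626 (stem cell, small intestine), -0.185 to -0.0211 (stem cell, large intestine), -0.057 to 0.134 (stem cell, wild-type segments), -0.18 to -0.0376 (goblet), -0.47 to 6.1 (hepatocyte), -0.15 to 0.0934 (claudin, both segments) and -0.303 to -0.0222 (claudin, wild-type segments).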

Other observations

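The tests in this part come from the comparisons fixed before, but the genes and the per-array levels shown were chosen only after the result was seen.

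Single genes outside the lists that passed changed in the knockout small intestine, while the fixed list of glucocorticoid response genes did not pass there by camera (median 0.33, adjusted p = 0.235) but passed by fry (adjusted p = 0.0479, and 0.0219 over both segments). Zbtb16, a zinc finger transcription factor induced by glucocorticoids, rose by 4.30 ± 0.39 (adjusted p = 0.00812), and Fkbp5, a co-chaperone of the glucocorticoid receptor, rose by 1.67 ± 0.38 (adjusted p = 0.0447), while Pck1, of gluconeogenesis, fell by 2.15 ± 0.25 (adjusted p = 0.0153). In the large intestine Zbtb16 had 2.33 ± 0.39 (adjusted p = 0.0994) and Fkbp5 1.31 ± 0.38 (adjusted p = 0.253), and over both segments Zbtb16 rose (adjusted p = 0.0424). S100g, the vitamin D-dependent calcium-binding protein of enterocytes, fell by 3.98 ± 0.56 in the small intestine (adjusted p = 0.0228) and had 0.07 ± 0.56 in the large. Ccl28, a mucosal chemokine, fell by 4.75 ± 0.24 in the small intestine (adjusted p = 0.002) and had 0.09 ± 0.24 in the large, with a difference between segments of 4.84 ± 0.33 (adjusted p = 0.0087). The intestinal transcription factor gene Cdx2 fell by 1.73 ± 0.36 in the small intestine (adjusted p = 0.0391). Ccl28 was well above background on 1 of the 2 knockout small intestine arrays.

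Krt20, a keratin of mature surface epithelium, rose in both segments, by 2.28 ± 0.25 in the small intestine (adjusted p = 0.0128) and by 2.04 ± 0.25 in the large (adjusted p = 0.0409).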
